A study of Mus musculus with 18 samples.

How the data were processed

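Total RNA from 18 TA muscle samples of male mice was measured on the nCounter mouse inflammation panel, per the labels, with 100 ng loaded per sample. Groups (tumor-bearing or not, in the C26, LLC and KPP models) and the letters A to C come from the sample titles. The deposited table has 266 rows: 254 genes, of which 6 are housekeeping genes (Cltc, Gapdh, Gusb, Hprt, Pgk1 and Tubb5), 8 negative and 4 positive controls. Gene names were checked against the RefSeq gene table of assembly GRCm38.p6, used for names only: 248 matched a symbol and 6 an older synonym. The names in the file are kept (Chi3l3 is now Chil3 and C1s is C1s1), except that Mef2c_Mm is written Mef2c. No position is given, since the sources used here name no genome build.

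The deposited values are a normalized signal, and how the authors made them is not given in the sources used here. What follows was read from the values. Within each model the 6 housekeeping genes have the same geometric mean in every sample (532.0 in C26, 591.2 in LLC and 1769.1 in KPP), so each model was scaled on its own to its housekeeping genes. Low values lie on steps of a sample's own size (100% of them within a tolerance of 0.1 of a step), which gives scale factors from 0.602 to 3.221 and the counts behind the values. In C26 and KPP a background was subtracted from each sample and low genes sit near 1. In LLC nothing was subtracted and values under 20 were written as 20, which holds for 118 to 123 of the 254 genes in each LLC sample; such values are bounds. Whole counts were not recovered for all genes because of the subtraction and the floor, so the planned count-based test was not run. Scale factors and floors differ between models, and no level is compared across them unless said. No 2 samples held identical values. Scanner and cartridge batches are not given in the sources used here.

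A gene was kept when at least 3 of the 18 samples reached 20, counting an LLC value only above its floor of 20; this kept 168 of 248 genes. Without that reading of the LLC floor the rule keeps all 248, which is the setting named no filter. The limit of 20 was set beforehand and is called background below. Negative controls reached at most 8.81 in C26, 15.0 in LLC and 11.75 in KPP. Their values look unscaled: whole counts in LLC, and whole counts less the background in C26 and KPP. Gene values were multiplied by the sample's scale factor. A value under 20 may still lie above the negative controls, but the units differ. Values were taken as log2(value + 1), and limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 18 samples (12 residual degrees of freedom), with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 168 genes of each contrast; the threshold was an adjusted p of 0.05, two-sided. The contrasts were tumor-bearing minus control in each model, their average, and the 3 differences between models. Every adjusted p of a gene comes from limma. Housekeeping genes and control probes were not tested. SE is limma's moderated standard error, and SD the spread of 3 deposited values.

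Group assignments, tests, filter, thresholds, the naming rule, 14 pathway lists, 9 cell type lists and the first set of alternatives below were fixed before the data were examined. Lists with at least 3 kept genes (19) were tested with limma's fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes; adjustment was over the 19 lists. Camera with an estimated correlation was run beside it, and results given with an estimated correlation are camera's. Camera asks another question, whether a list's genes move apart from the other tested genes. Those genes come from an inflammation panel and are no neutral background. A list without a camera call may therefore still have shifted by the question that fry asks. Genes are named by a rule: per comparison the 15 highest and 10 lowest fold changes among genes that passed, the 10 smallest p where fewer than 10 passed, any list member or housekeeping gene, and the 5 smallest p of each difference between models.

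The fits were tested on simulated data, 20 sets with 40 changed genes drawn with the spread of each real group. The shared fit over 168 genes recovered 51.9% of 2-fold and 83.5% of 4-fold changes in C26, 45.4% and 73.5% in LLC, and 57.6% and 87.8% in KPP. Of its calls 22.4% were false in C26, 11.6% in KPP and 1.0% in LLC. A fit of each model alone over its own genes above background gave 5.4% false calls in C26 (128 genes), 5.9% in LLC (129) and 7.1% in KPP (157). A shift given to the complement list was found in 20 of 20 sets, in which a mean of 1.65 of the 18 other lists was also called.

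The first set of alternatives was pseudocounts of 5 and 20, no filter and a minimum of 50, values under 20 set to 20, scaling to all 6 or to 4 housekeeping genes (without Gapdh and Pgk1), median centring, quantile normalization, the letters as a replicate block, moderation with trend and robust settings, a fold threshold of 1.5, separate fits per model, camera with a preset (0.01) and an estimated correlation, and leaving out each sample. Chosen after seeing the data were separate fits over the genes above background in that model, fry on separate fits, 1 variance weight per group, LLC floor values left out, and the sign of the C26 effect turned. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables read with pandas 2.3.3.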

Results

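Muscle transcripts were measured in mouse models of cancer cachexia, the loss of muscle and fat that accompanies many tumors. TA muscle of male mice was profiled on the nCounter mouse inflammation panel, an assay that counts color-coded probes bound to RNA without amplification, with 100 ng of total RNA per sample. The 18 samples form 6 groups of 3: tumor-bearing and non-tumor-bearing mice of each of 3 models. C26 mice (strain CD2F1) were injected with a colon carcinoma line, LLC mice (strain C57/B6) with the Lewis lung carcinoma line, and tumors in KPP mice (strain C57/B6) were induced with tamoxifen. Samples are named by group and the letter A, B or C of the labels. Counts behind the gene values ranged from 29690 in C26 tumor C to 402807 in KPP tumor B, and a value of 100 carried a counting error between 7.8% and 17.9%. Each model was normalized on its own, so levels are compared within a model. Of 248 panel genes, 168 rose above background in at least 3 samples and were tested. Fold changes are tumor-bearing over control on the log2(value + 1) scale, which understates changes of low genes. The labels do not say that every sample came from a separate mouse, and p-values measure the spread between samples.

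The C26 comparison asked how muscle of mice given C26 cells differed from that of controls of the same strain. Of 13 complement genes 8 were lower and 2 higher in the samples labelled tumor-bearing, of 6 genes of IL-1 and IL-6 reception 4 were lower, and of 18 MAP kinase cascade genes 4 were higher and 1 lower. By fry 4 of 19 lists shifted down, while no list moved apart from the other genes in camera with an estimated correlation (adjusted p = 0.93 or more). The complement list missed the threshold when scaled without Gapdh and Pgk1 (fry adjusted p = 0.077). Cfd, the complement protease that fat cells make in quantity, averaged 61.6 ± 22.4 (SD, n = 3) against 4330 ± 4580 in the controls, a log2 fold change of -5.63 (SE 0.77, adjusted p = 0.000253). Stat3, the transcription factor activated by IL-6 family cytokines, averaged 258 ± 18.5 against 904 ± 133 (-1.80, SE 0.23, adjusted p = 0.000253). Map2k6, a kinase that activates p38 MAP kinases, averaged 392 ± 9.40 against 85.0 ± 32.3 (2.26, SE 0.43, adjusted p = 0.00262). In all, 51 of 168 genes passed limma's test, 15 higher and 36 lower, and 69 had an unadjusted p under 0.05. The balance turned under each other scaling: 28 higher and 19 lower without Gapdh and Pgk1, 30 and 16 with median centring, and 29 and 21 with quantile normalization. Of 128 genes above background in C26, 54 had no overlap between the groups (42.2%, where chance gives 10%), 38 of them lower in all 3 samples labelled tumor-bearing.

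**Figure D1:**
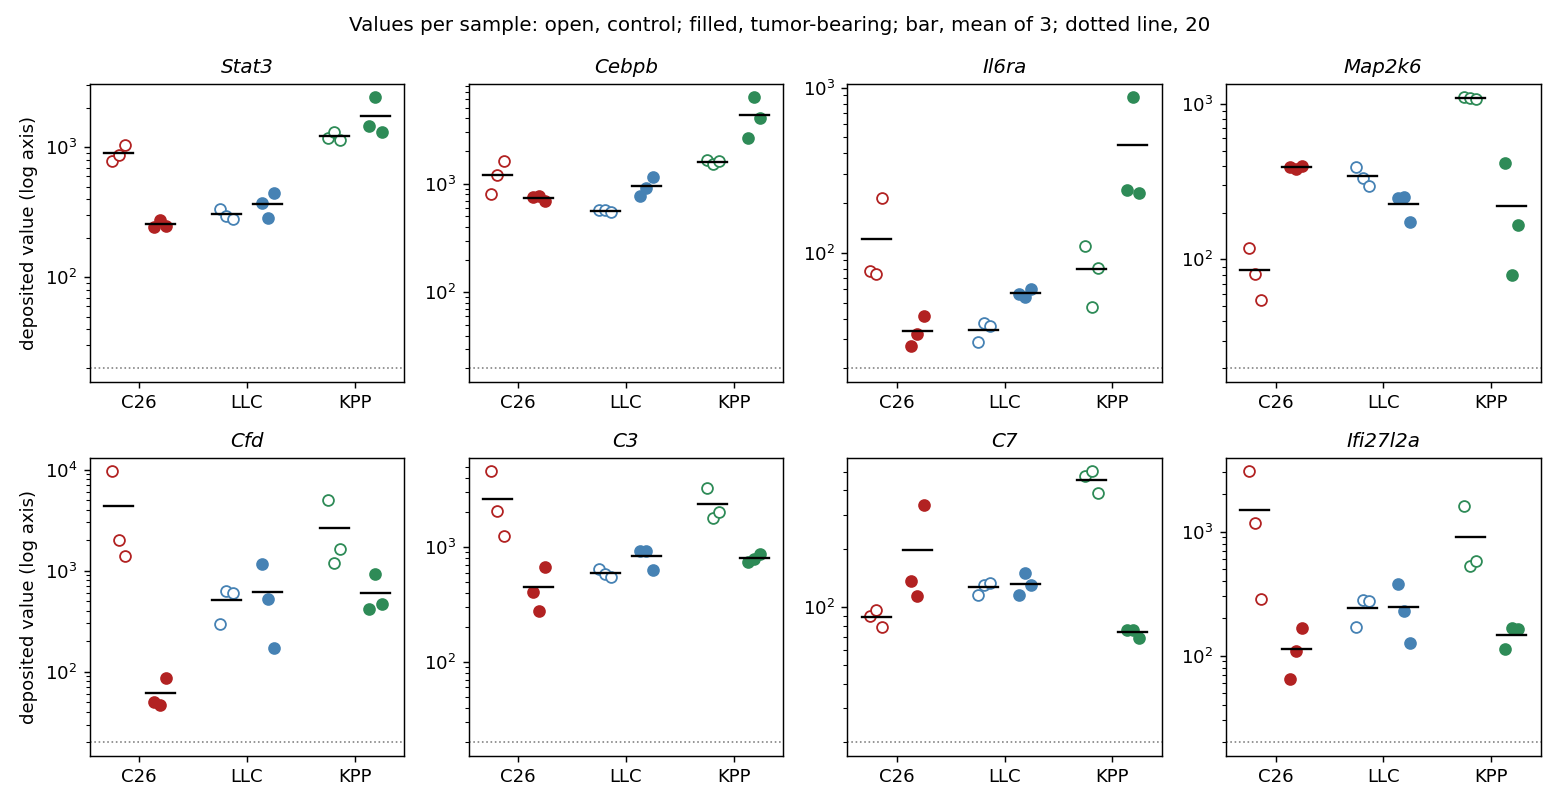
Deposited values per sample (log axis) of 8 genes in the 3 models; open points are controls, filled points tumor-bearing samples, bars the means of 3 and the dotted line the background limit of 20. In C26 the 3 samples labelled tumor-bearing lie below the 3 controls for Stat3 and above them for Map2k6, and in KPP the order of Map2k6 is the opposite.

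Complement was the list with the most C26 calls. Of 13 tested, 8 fell and 2 rose, with the same counts when adjusted over the list alone, and the list shifted down (median -1.70, fry adjusted p = 0.018; adjusted p = 0.93 with an estimated correlation). C4a was 56.4 ± 46.2 against 1120 ± 818 (-4.35, or -4.97 without tumor C) and C3, the central complement component, 449 ± 199 against 2620 ± 1720 (-2.43), while C7 (0.98) and Masp1 (0.96) rose. Ifi27l2a stood at -3.25. Probe sequences are not given, so signal from the close copies C4b and Ifi27l2b is not separated from that of C4a and Ifi27l2a. Of 6 genes of IL-1 and IL-6 reception, Stat3, Myd88 (-1.81), Il6ra (-1.66) and Il1r1 (-1.31) fell, and Cebpb, at -0.66, did not pass. With p adjusted over the list alone 5 fell, and the list shifted down (median -1.49, fry adjusted p = 0.0025; adjusted p = 0.93 with an estimated correlation). Among 13 NF-kB pathway genes Rela (-1.12), Relb (-1.43), Ripk2, Traf2 and Nod2 fell and Map3k7 rose, with no shift of the list (fry adjusted p = 0.10). That split of 1 up and 5 down became 3 and 2 without Gapdh and Pgk1, 2 and 0 with median centring and 2 and 1 with quantile normalization. Of 18 MAP kinase cascade genes Map2k6, Map3k7, Rps6ka5 and Mapkapk5 rose and Shc1 (-0.54; 0.02 with median centring, without passing) fell; adjusted over the list alone 5 rose and 1 fell (fry adjusted p = 0.092). Mapkapk5 averaged 18.5 in the samples labelled tumor-bearing and 1.73 in the controls, both under the preset limit of 20. The highest negative control of those samples was 4.79, without the scaling given to the genes. Of the 51 genes 10 had fewer than 3 of the 6 C26 samples above that limit: Mapkapk5, Nod2, Elk1, Ltb4r1, Mmp9, Il1b, Ccr1, Ly96, Tlr8 and Ptger3. Nod2, Ccr1, Tlr8 and Ptger3 also stood at the floor of 20 in every LLC sample, which lowers their spread in the shared fit by construction. The muscle and MEF2 list held 2 higher genes, the transcription factor Mef2c (1.16) and the small heat shock gene Hspb2 (0.77), and 1 lower, the deacetylase Hdac4 (-1.50), among 9 (fry adjusted p = 0.80).

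Markers of other cell types moved unevenly in C26. Of 10 macrophage and monocyte markers 6 fell, among them C1qa (-2.20), C1qb (-2.25), Tyrobp (-1.55) and Cd163 (-1.78). Adjusted over the list alone 8 fell, and the list missed the threshold (median -1.55, fry adjusted p = 0.052). In control A these markers were highest, with Tyrobp at 424 against 106 and 143 in controls B and C, Cfd at 9604 and Ccl8 at 1997. Without control A 46 genes passed, 32 of them among the 51, the folds of 15 of the 51 moved by over 1.5 times and the macrophage median stood at -0.87. Cfd then stood at -4.79, C1qa at -1.50, C1qb at -1.48, Tyrobp at -0.95 and Ifi27l2a at -2.45, each still passing, and Cd163 at -1.24 without passing. The neutrophil list (3 genes; Il1b and Mmp9 fell, and all 3 adjusted over the list alone) and the cytokine ligand list (3 genes; Il1b and Csf1 fell) shifted down with fry adjusted p = 0.035 and 0.018, against adjusted p = 0.93 for each with an estimated correlation. Il1b averaged 5.07 against 21.9 and Mmp9 5.36 against 12.8, near or under background. Among 7 fibroblast and connective tissue markers C7 and Masp1 rose and C1s and C3 fell (3 rose and 2 fell adjusted over the list alone, fry adjusted p = 0.68). Neither gene of the preset endothelial list passed (Flt1 0.06, Ptgir 0.64). The alternatively activated macrophage list had 2 of 5 genes lower (fry adjusted p = 0.12) and antigen presentation markers 0 of 3 (fry adjusted p = 0.82). The slow fiber gene Myl2 stood at 0.56 without passing.

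Further C26 lists held fewer calls and did not shift. Ccl8 (-3.81) and Ccl21a (-1.69) fell among 9 chemokines (fry adjusted p = 0.15), and Tlr8 and Ly96 among 8 Toll-like receptor genes (0.092). Ccl8 stood at -2.33 without control A and at -4.82 without control C, and Ccl21a, at -1.59, did not pass without control A. Of 11 immediate early and stress transcription factors Myc (-2.27) and Elk1 fell and Ddit3 (1.47, or 2.09 without control C), a factor of the unfolded protein response, rose (0.32). Mx1 (1.56) rose and Ifi27l2a fell among 16 interferon-stimulated genes (0.35). Mmp3 (-4.28) and Mmp9 fell and Smad7 (0.96), an inhibitor of TGF-beta signaling, rose among 10 TGF-beta and matrix genes (0.80). Mmp3 stood at -3.40 without control A, -3.29 without tumor B and -5.26 without tumor A. Mmp9 stood at -2.09 without tumor C and, without passing, at -0.83 without tumor B. These lists each held 1 or 2 calls: Ltb4r1 up and Ptger3 down of 10 eicosanoid genes (0.70) and Nos2 (1.34) up of 7 oxidative stress genes (0.69). Irf5 (2.36, or 2.96 without control A) also rose. Adjusted over the list alone, 1 chemokine fell, 1 interferon-stimulated gene fell and none rose, and no eicosanoid gene passed; the remaining lists without such a count had equal ones.

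Among the 6 housekeeping genes to which the values were scaled, Gapdh (0.79) and Pgk1 (0.85) were higher in the samples labelled tumor-bearing. Gusb (-0.61), Hprt (-0.37), Cltc (-0.36) and Tubb5 (-0.29) were lower. The scaling fixes their geometric mean, so a rise of the former cannot be told from a fall of the latter. The median of all genes stood at -0.31. Scaled without Gapdh and Pgk1 that median was 0.09, with median centring 0.25 and with quantile normalization 0.16, and 34, 31 and 36 of the 51 were still called. The list of IL-1 and IL-6 reception genes shifted down under all 3 scalings (fry adjusted p = 0.002, 0.013 and 0.011), and no list called under them held with an estimated correlation (adjusted p from 0.60 up). Complement (0.077) and the cytokine ligands (0.065) missed the threshold without Gapdh and Pgk1, the cytokine ligand list held 0 single calls under all 3, the neutrophil list missed it under all 3, the MAP kinase and the TGF-beta and matrix lists shifted up under all 3, and the fibroblast median turned from -0.07 to 0.30, 0.49 and 0.44. In the immediate early list, 1 up and 2 down became 3 and 1, 3 and 1, and 2 and 1, and in the TGF-beta and matrix list 3 and 1 under each. Counts behind the C26 values were 75498 to 94955 in controls and 29690 to 50733 in the samples labelled tumor-bearing. The shared estimate of spread is too small for C26, whose controls varied most (median SD 0.64 on the log2 scale against 0.11 in LLC controls): a fit of the 6 C26 samples alone called 4 genes (Stat3, Cfd, C4a and Map2k6), or 6 of 128 above background in C26, which add Nos2 and Maff (-1.16), the latter not called by the shared fit. In simulated data the shared fit's C26 calls were 22.4% false. Without tumor A 31 genes passed and without tumor B 30, with 1 list shifted in each case, 2 without control A and 7 without control B, none with an estimated correlation (adjusted p = 0.52 or more), and 24 of the 51 passed whichever of the 6 samples was left out.

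The LLC comparison asked the same of mice given LLC cells. No gene of 168 passed limma's test in the fit of all 18 samples, and 4 had an unadjusted p under 0.05: Cebpb, Ptgir, Ccl24 and Irf5. Cebpb, a transcription factor of the acute phase response, averaged 948 ± 195 (SD, n = 3) against 564 ± 12.7 in controls (0.73, SE 0.29). The next smallest p were those of Pdgfa (-0.38), Ripk2 (0.56), Chi3l3 (-1.95), Masp1 (-0.63), Flt1 (0.38) and Prkca (-0.50). None of the 19 gene lists shifted, with fry adjusted p from 0.89 to 0.98, and the largest list medians were those of alternatively activated macrophage markers (0.91) and macrophage and monocyte markers (0.44). Of 129 genes above background in LLC, 35 had no overlap between the groups (27.1%, where chance gives 10%). The adipocyte marker Cfd stood at -0.03, the slow fiber marker Myl2 at 1.20 and Ptgir, of the preset endothelial list, at 0.64.

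The shared spread is too large for LLC, whose samples varied least. A fit of the 6 LLC samples alone over the 129 genes above background there, chosen after seeing the data, called 8 genes, 6 higher and 2 lower, while the same fit over 168 genes called 0 (26 unadjusted). Higher were Retnla (1070 ± 218 against 535 ± 88.4) and Ccr2 (105 ± 24.7 against 56.0 ± 4.18), both made by macrophages or monocytes, H2-Eb1 (349 ± 38.0 against 207 ± 22.4), the IL-6 receptor gene Il6ra (56.9 ± 3.31 against 34.2 ± 4.72), Cebpb and Ptgir, with adjusted p from 0.0445 to 0.0489. Lower were Irf5 (42.5 ± 19.5 against 95.8 ± 5.96, adjusted p = 0.0489) and Chi3l3 (adjusted p = 0.00318), which was 91.2 ± 22.4 in controls and at the LLC floor of 20 in 2 of 3 tumor-bearing samples, so its fall is a lower bound. In simulated data 5.9% of the genes this fit called in LLC were false. Fry on the 6 LLC samples over the 168 genes, where limma's test called 0 genes, moved 4 lists up: immediate early transcription factors (fry adjusted p = 0.012), interferon-stimulated genes and antigen presentation markers (0.028 each) and macrophage and monocyte markers (0.044). In the fit of all 18 samples these lists had adjusted p = 0.99 with an estimated correlation. Of the 3 antigen presentation genes 1, H2-Eb1, was above background in LLC. So were 9 of 16 interferon-stimulated genes, 9 of 11 immediate early factors and 8 of 10 macrophage and monocyte markers. These list tests thus included genes at the LLC floor.

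The KPP comparison asked how muscle of mice with tamoxifen-induced tumors differed from that of KPP controls. Of 7 connective tissue markers 3 were lower and 1 higher in tumor-bearing mice, and the IL-6 receptor gene and Cebpb were higher. C7, a terminal complement component, averaged 73.8 ± 4.34 (SD, n = 3) against 455 ± 59.9, a log2 fold change of -2.60 (SE 0.30, adjusted p = 7.06e-05). Map2k6 was 220 ± 175 against 1090 ± 13.7 (-2.61, SE 0.43, adjusted p = 0.0021), Il6ra 448 ± 368 against 79.5 ± 31.5 (2.27, SE 0.49, adjusted p = 0.0117) and Cebpb 4300 ± 1810 against 1600 ± 71.7 (1.34, SE 0.29, adjusted p = 0.0117). In all, 19 of 168 genes passed limma's test, 9 higher and 10 lower, and 42 had an unadjusted p under 0.05. Of 157 genes above background in KPP, 47 had no overlap between the groups (29.9%, where chance gives 10%).

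Of 7 fibroblast and connective tissue markers in KPP, C7, C1ra (-1.59) and C3 (-1.51) fell and Masp1 (1.18) rose. Adjusted over the list alone 4 fell, and the list shifted down (median -0.97, fry adjusted p = 0.024; adjusted p = 0.76 with an estimated correlation). Each of its 7 genes stands in another list too, so the 13 complement genes held the same 3 falls and 1 rise (4 and 1 adjusted over the list alone; fry adjusted p = 0.14). The chemokines Cxcl9 (-2.79) and Ccl5 (-3.51, or -4.29 without control A) fell among 9 (fry adjusted p = 0.12). Cxcl9 (7.89 ± 2.40 from 65.8 ± 34.4), Ccl5 (1.37 ± 0.322 from 32.9 ± 22.1) and Ptger3 were under background in all 3 tumor-bearing samples. Their folds depend on the background that was subtracted and on the pseudocount. For Ccl5 and for Ptger3, 2 of the 3 controls were above background. Cxcl9 and Ptger3 stood at the floor of 20 in every LLC sample, which lowers their spread in the shared fit by construction. Ifi27l2a (-2.44) and Cxcl9 were the calls among 16 interferon-stimulated genes (0.60). Il6ra and Cebpb rose among 6 genes of IL-1 and IL-6 reception, where Stat3 stood at 0.46 without passing (median 0.57, fry adjusted p = 0.12). Maff (1.77) and Cebpb rose among 11 immediate early factors (3 rose adjusted over the list alone; 0.15), and Maff and Nfe2l2 (0.59), the regulator of antioxidant genes, among 7 oxidative stress genes (0.15). The endothelial marker Flt1, a VEGF receptor, rose from 873 ± 128 to 1660 ± 211 (0.93), and Ptgir stood at 0.72; adjusted over the list alone both rose. Bcl2l1 (1.41), which opposes apoptosis, and Tlr4 (1.78) rose, the latter among 8 Toll-like receptor genes (0.71). Chi3l3 (3.26) rose to 152 ± 169, the call among 5 alternatively activated macrophage markers (0.95). Macrophage and monocyte markers held 0 calls of 10 (median 0.05, fry adjusted p = 0.95).

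The other KPP lists held at most 1 call each, and none shifted. Mmp9 (-1.56) fell among 10 TGF-beta and matrix genes (fry adjusted p = 0.95) and 3 neutrophil markers (0.71), Ptger3 (-2.95) among 10 eicosanoid genes (0.95), Tradd (-0.81) among 13 NF-kB genes (0.95; 0 adjusted over the list alone) and Map2k6 among 18 MAP kinase genes (0.95). Muscle and MEF2 genes (0.71), cytokine ligands (0.27; 1 fell adjusted over the list alone) and antigen presentation markers (0.51; 1 fell adjusted over the list alone) held 0. Complement, chemokine, IL-1 and IL-6 reception and other lists shifted under some scalings, 2 lists without Gapdh and Pgk1, 7 with median centring and 5 with quantile normalization, and the fibroblast list shifted down under all 3; none held with an estimated correlation (adjusted p from 0.096 up). Cfd, the only adipocyte marker, stood at -1.93 without passing limma's test (SE 0.77, adjusted p = 0.13, unadjusted p = 0.0247) and Myl2 at 0.15. In 7 of the 19 KPP lists, and in 1 of C26 and 1 of LLC, the median, mean and test direction of the list differed in sign. None of the 9 T cell markers rose above background in any model.

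KPP tumor B stood apart, with Fos at 2310 against 137 and 311 in tumor A and C, Il6ra at 873 against 242 and 230, and Maff at 410 against 69.9 and 126. Without it 13 genes passed, and Il6ra stood at 1.64, Cebpb at 1.03 and Map2k6 at -2.04, each still past the threshold, while Chi3l3 (2.34), Tlr4 (1.14), Maff (1.06), Nfe2l2, Masp1, C3, Ifi27l2a, Mmp9 and Tradd no longer passed. Without control A 11 genes passed, without control C 10 and without tumor C 8. Whichever of the 6 KPP samples was left out, 7 genes passed: Bcl2l1, C7, Cebpb, Cxcl9, Flt1, Il6ra and Map2k6. Chi3l3 (2.10) did not pass without control C, Ptger3 (-2.17) did not without control A, and without tumor A Tlr4 stood at 2.65 and Map2k6 at -3.23. Chi3l3 passed at 4.09 without control A and at 4.07 without tumor A, and Ptger3 at -3.63 without control B. The fibroblast list lost its call without control A, control B or tumor C, and without tumor A 3 lists shifted, none with an estimated correlation (adjusted p = 0.79 or more). A fit of the 6 KPP samples alone called 7 genes, all lower (C7, Cxcl9, C1ra, Ccl5, C3, Mmp9 and Ifi27l2a), and none of the 9 higher ones, and in simulated data 11.6% of the shared fit's KPP calls were false.

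**Figure D2:**
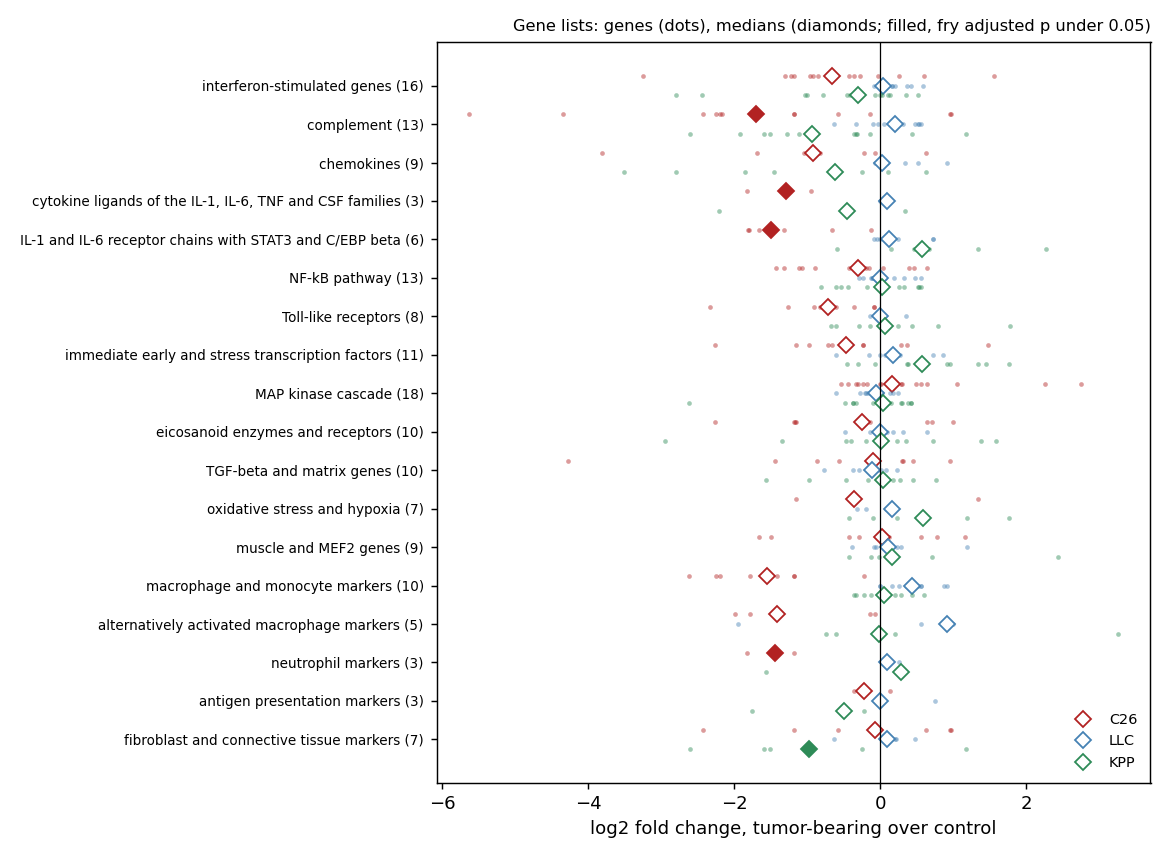
Log2 fold change (tumor-bearing over control) of each gene (dots) in 18 of the 19 gene lists, with list medians as diamonds, by model; the number tested stands in parentheses. Filled diamonds mark lists with a fry adjusted p under 0.05, which are 4 in C26, 0 in LLC and 1 in KPP. In camera with an estimated correlation 0 of these moved apart from the other genes (adjusted p = 0.76 or more).

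A comparison of the models asked whether tumors changed the same genes. No gene passed in all 3 models, since limma's test called 0 in LLC (4 at an unadjusted p under 0.05). C26 and KPP shared 8, of which C3, Ifi27l2a, Mmp9 and Ptger3 fell and Masp1 rose in both, and C7, Il6ra and Map2k6 went opposite ways. These 5 and 3 rest on the C26 labels, and would be 3 and 5 with the sign of the C26 effect turned. In the 6 fits without 1 KPP sample Mmp9 passed 0 times, C3 and Ifi27l2a 1 time, and Masp1 and Ptger3 2 times. The genes that went opposite ways passed in all 6. In the 6 fits without 1 C26 sample C3, Ifi27l2a and Map2k6 passed 6 times, C7 4, Il6ra 3, Masp1 and Mmp9 2 and Ptger3 1. Mmp9 was under background in every C26 sample. Independent lists would share 2.14 falls, 0.80 rises and 2.82 opposite calls. Across the 168 genes, which are not independent replicates, fold changes of C26 and KPP correlated with Pearson's r = 0.04 (Spearman's coefficient -0.01), those of C26 and LLC with r = -0.17 (Spearman's -0.28) and those of LLC and KPP with r = 0.04 (Spearman's 0.15). Averaged over the models, 16 genes passed limma's test, 4 higher and 12 lower, or 8 and 9 with median centring. With the sign of the C26 effect turned, a setting added after seeing the data, 20 passed, 15 higher and 5 lower. Ifi27l2a (-1.93, SE 0.40, adjusted p = 0.0103), C3 (-1.16) and Cfd (-2.53, SE 0.44, adjusted p = 0.00785) fell and Smad7 (0.55) rose. In LLC, however, C3 was higher (0.47), and Cfd (-0.03) and Ifi27l2a (-0.09) barely moved. Of the 16 genes 9 had the same sign in all 3 models. Ptgir, the prostacyclin receptor gene, passed in no single model in the fit of all 18 samples and stood at 0.64, 0.64 and 0.72 in C26, LLC and KPP (mean 0.67, SE 0.15, adjusted p = 0.0161). The count of 16 lay between 6 and 22 when single samples were left out. It dropped to 8 and 9 without C26 tumor A or B, to 6 without LLC control B, LLC control C, LLC tumor C or KPP control C, to 7 without KPP control A, to 8 without LLC tumor B and to 9 without KPP tumor C.

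**Figure D3:**
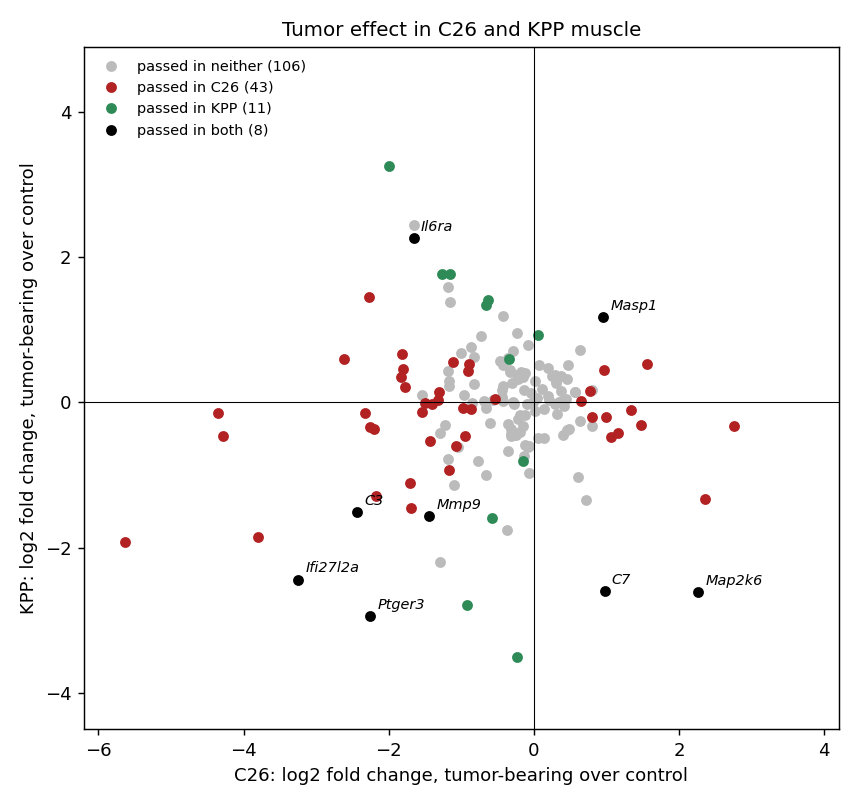
Log2 fold changes (tumor-bearing over control) of the 168 genes in C26 (horizontal) and KPP (vertical), colored by the model in which they passed. The 8 genes that passed in both are named; C7 and Map2k6 lie at lower right and Il6ra at upper left.

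Differences between the tumor effects were tested directly. The effect in C26 differed from that in KPP for 27 genes and from that in LLC for 25, and the effects in LLC and KPP differed for 1, C7 (2.65, SE 0.43, adjusted p = 0.0031). Map2k6 differed between C26 and KPP by 4.88 (SE 0.61, adjusted p = 8.97e-05), C7 by 3.57, Stat3 by -2.26, Il6ra by -3.93 and Nos2 by 1.44. Of the 27 genes, 24 had opposite signs in C26 and KPP. With the sign of the C26 effect turned 32 genes differed between C26 and KPP, 7 of them among the 27, and 8 between C26 and LLC. Between C26 and LLC, Stat3 differed by -2.05 (SE 0.33, adjusted p = 0.00307), Cfd by -5.61, C4a by -4.88, C3 by -2.91 and Nos2 by 1.54. Nos2 was under background in all 3 C26 controls and at the LLC floor in all 3 LLC tumor-bearing samples, so its differences rest in part on values at or under the limit. The list of IL-1 and IL-6 reception genes differed between C26 and KPP (median difference -2.13, fry adjusted p = 0.0013) and between C26 and LLC (-1.59, fry adjusted p = 0.0097), against adjusted p = 0.91 and 0.86 with an estimated correlation. Without C26 control A 42 genes differed between C26 and KPP and without KPP tumor B 17, without KPP tumor A 6 differed between LLC and KPP, and the count between C26 and LLC fell to between 8 and 15 without C26 tumor A, C26 tumor B or any single LLC sample.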

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

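The splits of the samples were planned; the tests of exchanged labels, of the housekeeping scaling, of control A and of the muscle share in C26 were chosen after the result was seen. The tumor effect differed between C26 and LLC for 25 genes by a test of the difference itself, with the smallest p for Stat3 (-2.05), Nos2 (1.54), Cfd (-5.6), C4a (-4.88) and C3 (-2.91). Between C26 and KPP it differed for 27 genes, first C7 (3.57), Map2k6 (4.88), Stat3 (-2.26), Il6ra (-3.93) and Nos2 (1.44), and between LLC and KPP for 1, C7 (2.65). No group has 4 or more samples, so single samples were not tested for distance from their group.

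Other splits of the same samples were counted, the real one included. In C26 1 of 10 splits of the 6 samples gave as many genes (51, next 2) and 1 of 10 as many lists (4, next 1), in KPP 1 of 10 as many genes (19, next 0) and 1 of 10 as many lists (1, next 0), and in LLC 10 of 10 gave as many genes and lists (0, next 0). With 10 splits the share cannot be under 0.1. Tumor status was exchanged within each model for the average, and model labels within tumor status for the differences, after each gene's mean in each model was removed. For the average over models 1 of 100 drawn splits gave as many genes (16, next 5), so chance as the source of the whole count is argued against. Turning the sign of the C26 effect alone is also such a split. It was not among those drawn and gave more than 16 genes. The count therefore says nothing on a direction that the models share. For C26 against LLC 1 of 100 did (25, next 0), and for C26 against KPP 1 of 100 (27, next 18). For LLC against KPP 2 of 100 did (1, next 1), a single gene that 1 other split matched in number. Spreads and floors differ between models, so samples with exchanged model labels are not alike. The splits therefore cannot exclude chance for the differences between models. For genes changed in all 3 models the real count is 0, which all 100 splits must reach (next 0), as in LLC, so those splits say nothing about chance.

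Of the 27 genes whose effect differed between C26 and KPP 24 had opposite signs, which selection for a difference favors. Of the 8 genes that passed in both models 5 went the same way and 3 opposite ways, where independent lists give 2.82. Those 5 passed in KPP in at most 2 of the 6 fits without 1 KPP sample. The housekeeping scaling as the whole cause is argued against, since 19 of the 27 still differed when Gapdh and Pgk1 were left out, 17 of them with opposite signs. An exchange of control and tumor labels in C26 stays open: over 72 genes the C26 samples labelled control lay farther from the LLC and KPP controls (1.11 ± 0.25, root mean square log2 distance) than those labelled tumor-bearing (0.61 ± 0.06), a difference of 0.49, and all 3 of the latter were closer. KPP and LLC samples were measured against the controls of the other models, which include the C26 samples labelled control. KPP tumor-bearing samples lay farther than KPP controls (0.99 ± 0.06 against 0.57 ± 0.11), but LLC ones did not (0.51 ± 0.17 against 0.59 ± 0.05). Both results rest on the C26 labels in doubt, so they do not weigh on an exchange. Of the genes called in KPP, 7 of the 9 that rose and 8 of the 10 that fell were negative in C26. Models were normalized separately, and 3 samples against 3 allow no exact p under 0.1. The 0.49 therefore cannot be told apart from a real C26 response. The strain (CD2F1 against C57/B6) and the tumor type differ with the model and may also account for it, untested.

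In the C26 samples labelled tumor-bearing Cfd, 8 of 13 complement genes and 6 of 10 macrophage markers passed as lower; the macrophage list missed the threshold (fry adjusted p = 0.052), and the complement list missed it with an estimated correlation (adjusted p = 0.93) and without Gapdh and Pgk1 (0.077). Control A alone as the cause is argued against, since 7 of the 8 complement genes called lower still passed without it and Cfd stood at -4.79, although 3 rather than 6 macrophage markers passed. If a lower share of muscle in the C26 controls raised markers of every other cell type alike, both list medians would fall alike. Macrophage markers had a median of -1.55 (10 markers) and fibroblast markers one of -0.07 (7 markers). The exact permutation p was 0.0096 over 19448 arrangements of genes, two-sided. Without control A the medians were -0.87 and 0.31 (exact p = 0.041), and leaving out each other C26 sample gave at most 0.045. The arrangements treat genes of the same samples as independent, and added tissue need not hold both cell types alike. A lower share of muscle therefore stays open. Exchanged labels (0.49 above) stay open too, and so does tumor status itself, for which no test beyond the comparison was run.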

How the results depend on the processing

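The separate fits over each model's own genes, fry on separate fits, the group weights, the LLC floor values left out and the turned C26 sign were chosen after the result was seen. Scaling to all 6 housekeeping genes changed nothing, as the values are already scaled to them. Of the genes called in any comparison, under the pseudocounts, scalings and left-out samples, 1 changed sign: Shc1 in C26, from -0.54 to 0.02 with median centring. With a pseudocount of 20, 6 genes differed between LLC and KPP. Without a filter 12 differed between C26 and LLC and 1 list shifted in C26. With values below 20 set to 20, 4 genes differed between LLC and KPP, r of C26 and LLC was -0.29, and 2 lists shifted in C26 and 2 in KPP. Lists shifted in KPP were 2 when scaled without Gapdh and Pgk1, 7 with median centring (which gave 3 genes between LLC and KPP) and 5 with quantile normalization. With the letters as blocks, which the correlations of same-letter samples (-0.34 to 0.24) do not bear out as pairs, 2 genes passed in KPP and 0 on average, 2 differed between C26 and LLC, 17 between C26 and KPP and 0 between LLC and KPP, and 2 lists shifted in C26 and 0 in KPP. Separate fits called 4 genes in C26 and 7 in KPP; over each model's own genes, 6 in C26, 8 in LLC and 6 in KPP. With 1 variance weight per group 25 genes passed in C26, 1 in LLC and 9 between LLC and KPP, and 3 lists shifted in KPP. With LLC floor values left out 38 of the 51 C26 calls and 10 of the 19 KPP calls remained. Genes at that floor in every LLC sample add no spread there, so their spread in the shared fit is lowered by construction. How much of the loss this accounts for was not tested. With the sign of the C26 effect turned 8 genes differed between C26 and LLC. Fry on separate fits moved 1 list in C26 and 4 in LLC, camera with a preset correlation 0 in C26 and 4 in KPP, and with an estimated correlation 0 in C26 and 0 in KPP. Fewer degrees of freedom (4 against 12) belong to the separate fits by construction. Apart from that and the LLC floor, the cause of the changes was not tested. For each result, only the samples of the models it covers were left out in turn. This gave 30 to 53 genes in C26, 0 in LLC, 8 to 16 in KPP, 6 to 22 on average, 8 to 31 between C26 and LLC, 17 to 42 between C26 and KPP and 1 to 6 between LLC and KPP. Lists numbered 1 to 7 in C26, 0 in LLC and 0 to 3 in KPP. The r of C26 and KPP ran from -0.13 to 0.21, of C26 and LLC from -0.24 to -0.06 and of LLC and KPP from -0.02 to 0.08. Fits without a sample of another model are outside these ranges, and all 19 KPP calls still passed without C26 control A. The planned count-based test was not run. Depth limits low genes: a value of 20 stands for 9.2 counts in C26 tumor C and 6.2 in KPP control B.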

Other observations

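Hspb1, Gnas and the Gapdh shares were singled out after their values were seen, and no further tests were run on them. Cytokine transcripts themselves were mostly under background in TA muscle: of 12 ligands of the IL-1, IL-6, TNF and CSF families, Il1b, Il18 and Csf1 were kept, and Il6, Tnf, Il1a, Il11, Csf2 and Csf3 were under background in every model. Of 19 chemokines 9 were kept. Toll-like receptor genes above background numbered 2 in C26, 1 in LLC and 8 in KPP, and interferon-stimulated genes 8, 9 and 15. The same limit was used on unlike scales (housekeeping geometric mean 532.0 in C26, 591.2 in LLC and 1769.1 in KPP). These numbers therefore do not compare the models. The G protein subunit gene Gnas was among the highest genes in controls, at 4170 ± 643 in C26, 4740 ± 151 in LLC and 17000 ± 929 in KPP (SD, n = 3), on scales that differ between models.

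Hspb1, a small heat shock protein gene abundant in muscle, reached 38500 ± 31700 in KPP tumor-bearing samples against 3720 ± 175 in controls without passing (2.44, adjusted p = 0.118). Its values were 2591 in tumor A, 50741 in tumor B and 62299 in tumor C. Gapdh made up 30.7%, 11.8% and 18.3% of the gene values in those samples, and in C26 10.3% to 16.7% in controls against 25.2% to 26.1% in the samples labelled tumor-bearing.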
